A study of Mus musculus with 25 samples.

How the data were processed

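Liver RNA of 25 mice (5 animals in each of 5 groups, flash frozen tissue, Trizol extraction, TruSeq Stranded mRNA LT libraries) was analysed from a single deposited table. The values are RPKM computed by the authors, that is reads per kilobase of gene model scaled to the reads of the library; which reads that total counts was not stated. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a to mm10 and counted with HTSeq. The strand setting of the counting and the treatment of reads that match several genes were not stated, so values of near-identical genes (Mup, Cyp2c, Cyp2a and H2 families) are uncertain. Groups were taken from the sample labels.

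The table held 60354 rows. Of these, 36222 carried a name and no value, among them 4 summary rows of the counting tool and 25479 rows named by an Ensembl identifier. Of the 24132 rows with values, 6272 were 0 in every library, 1 (Plin2) was infinite and 24 bore a date number instead of a gene symbol; Plin2 and the date-numbered rows were left out. No mitochondrially encoded gene was in the table (0 members). Whole read numbers could be recovered for all 17859 genes with a finite value above 0, within 0.02 reads, from the spacing of low values (up to 0.3 RPKM). By this recovery, 21.8 to 27.59 M reads (megareads) per library lay behind the scaling (mean 24.87 ± 1.42 SD, n = 25), of which 14.5 to 18.64 M (62.3 to 68.2%) fell on genes with values. At 1 kb a single read in the first young WT library was worth 0.0386 RPKM.

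Genes with at least 1 RPKM in at least 5 of the 25 libraries were tested (9372). Log2 of RPKM plus 0.5 was fitted with limma 3.58.1 in R 4.3.3, in a single model of 5 groups (20 residual degrees of freedom) with an intensity trend, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. In all, 7 comparisons of groups were made, and the difference between the 2 comparisons of old mice with their own young partners was tested as an interaction. Of 43 fixed gene lists of pathways and cell types, the 37 with at least 4 tested members were tested with camera (limma) at a preset correlation of 0.01, with an estimated correlation, and with fry. Results of fry are not reported here. For each list, members were also adjusted over the list alone, and medians were taken relative to all tested genes. Manf and the Alb share were compared by exact two-sided permutation over every assignment of 5 against 5 livers. Sets of up to 200 genes per direction linked to age were taken from an age comparison that shares no library with the comparison they were tested in. Gene positions are from GENCODE M21. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

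Genes were named by a rule. Manf was always named. For the comparisons within an age and for old mice with young WT partners against those partners, the 8 largest positive and 8 largest negative log2 differences among passing genes with a mean of at least 1 RPKM were named, predicted genes left out. Where fewer passed in a direction, all that passed and up to 4 with the lowest p that did not pass were named. Up to 4 members of each described list were added. Some genes that the rule selects are not reported here. The filter, model, lists, comparisons, naming rule and alternatives were fixed before the data were examined. The phase score, the genes whose single levels are shown (Acta1 and Prss2 among them) and some alternatives, given in the closing part, were chosen after values had been seen.

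The analysis was tested on simulated data of the same depth and spread per gene, with 200 changed genes per comparison. Genes were drawn independently, without correlation between genes or a shift of scale between groups. The rates that follow do not cover either, and the false share in the real data may be higher. Across the 7 comparisons, 58.2 to 66.7% of genes changed by log2 0.5 were called, 82.1 to 92.5% of those changed by 1 and 93.8 to 100.0% of those changed by 2. Between 3.1 and 6.9% of calls were false, at most 1 gene was called where nothing differed, and the fitted change of genes moved by log2 2 was 0.87 to 0.89 of the true change. Alternatives covered the added constant, the filter, median-of-ratios scaling, the libraries in the model, weights per library, the replicate number as a block, the size of the age-linked sets, and each library left out in turn.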

Results

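Liver RNA was sequenced from 25 C57BL/6 mice in 5 groups of 5 animals after 5 weeks of parabiosis, in which a pair of mice is joined so that both share a circulation. Old mice (21 months, all wild type, WT) had been joined to another old mouse (the old-old group), to a young WT mouse, or to a young mouse heterozygous for Manf. Both kinds of young partner (5 months) were profiled as well. The libraries rested on 22.8 to 24.2 M (megareads) in the old-old group, 24.3 to 26.9 M in old mice with young WT partners and 21.8 to 27.6 M in old mice with heterozygous partners. The young WT and young heterozygous libraries rested on 24.2 to 25.9 and 23.3 to 25.9 M. Across genes, libraries of the same group correlated at 0.967 to 0.992, and no pair held identical values. Levels are the deposited RPKM, given as mean ± SD over 5 livers. Log2 differences are of RPKM plus 0.5, given ± SE from limma with its adjusted p. They understate the change of genes with low RPKM.

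Manf, which encodes a secreted protein induced by stress in the endoplasmic reticulum (ER), was the gene targeted in the heterozygous partners (chromosome 9, 106838312 to 106891979, mm10). It stood at 4.47 ± 1.11 RPKM in young heterozygous livers and 15.3 ± 6.47 RPKM in young WT livers, a ratio of 0.293 between the means. The heterozygous libraries read 5.23, 5.94, 3.61, 4.33 and 3.25 RPKM, all below the lowest WT library at 9.78 RPKM. Old livers, all WT, were at 17.6 ± 2.46 RPKM with a young WT partner, 7.12 ± 1.81 RPKM with a heterozygous partner and 8.86 ± 2.53 RPKM with an old partner. The log2 difference was -1.60 between the young groups, -1.27 between old livers with heterozygous and with WT partners, and 0.99 between old livers with WT and with old partners. Each of these had an exact two-sided permutation p = 0.00794, the smallest that 5 against 5 livers can give, and 0.0185 after Benjamini-Hochberg adjustment over 7 comparisons. Old livers with heterozygous partners were at -0.29 against old-old livers (exact p = 0.262). Against the young livers they had been joined to, old livers were at 0.28 in the WT pairs (exact p = 0.333) and 0.61 in the heterozygous pairs (exact p = 0.0318, adjusted 0.0556). Which old mouse was joined to which young mouse was not given, so these tests compare the groups without matching partners. Old-old livers were at -0.70 against young WT livers, with an exact p = 0.0635 (0.0397 at -0.79 after median-of-ratios scaling). Limma's adjusted p was 0.0488 there, a call lost in 5 of 10 omissions of a single library.

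**Figure D1:**
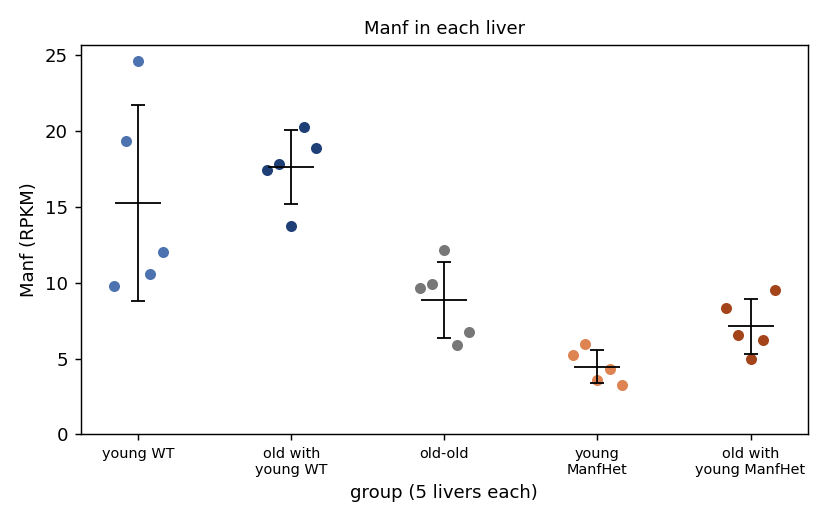
Manf level in RPKM for each of the 25 livers by group, with the mean and SD of 5 livers as black bars. Young heterozygous livers average 4.47 RPKM, and old livers average 17.6 RPKM with a young WT partner against 7.12 RPKM with a heterozygous partner.

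Clock genes differed between pair types in livers of both ages. A phase score, the mean log2 level of Arntl, Clock, Npas2, Nfil3 and Cry1 minus that of Dbp, Tef, Hlf, Per1, Per2, Per3, Ciart, Nr1d1, Nr1d2 and Usp2, was defined after these genes had been seen to differ. It averaged -1.75 ± 0.43 in young WT livers and -1.19 ± 0.60 in the old livers joined to them. In young heterozygous livers it averaged -3.46 ± 0.48, in the old livers joined to them -3.57 ± 0.43, and in old-old livers -3.26 ± 0.30 (SD, n = 5 each). Since the score was made from genes seen to differ, no p is given for it. The sources used here give no time of collection.

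**Figure D2:**
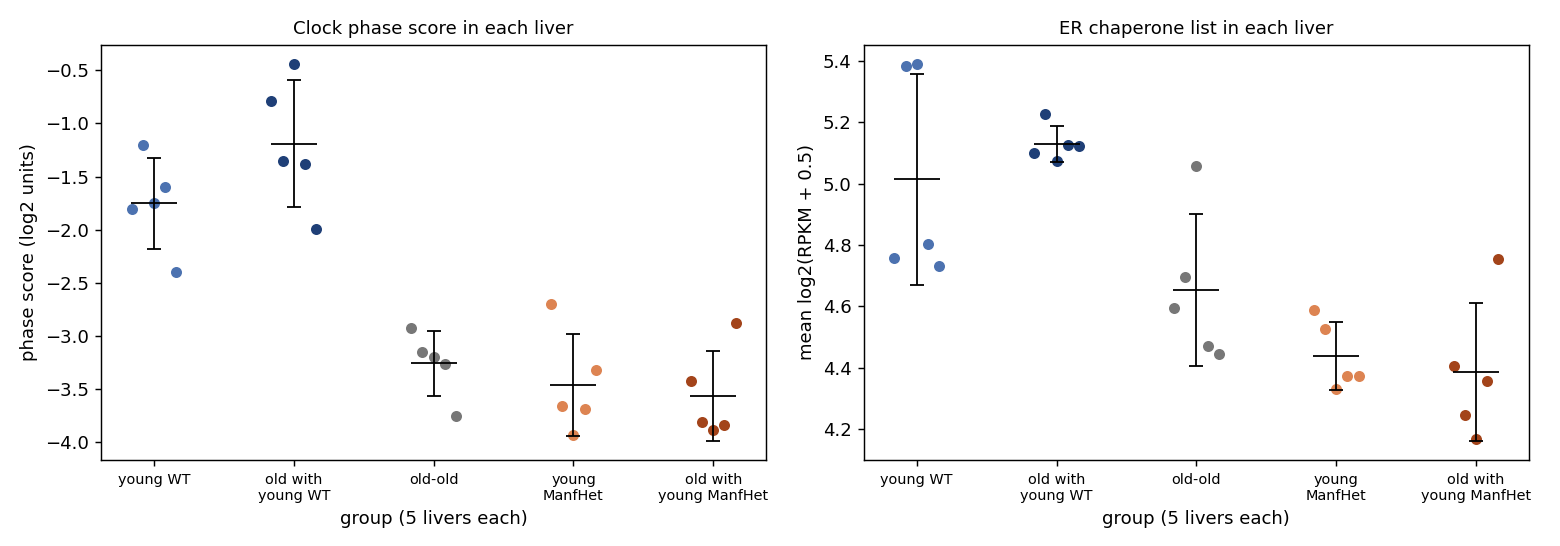
Clock phase score (left, log2 units) and mean level of the ER chaperone list (right, log2 of RPKM plus 0.5) in each liver by group, with the mean and SD of 5 livers as black bars. The phase score averages -1.75 and -1.19 in the young WT and old livers of WT pairs and lies at -3.26 or below on average in the other 3 groups.

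The first comparison sets a young WT partner against an old partner, in the old liver. Arntl, the core activator of the circadian clock, rose from 0.287 ± 0.0732 to 1.74 ± 0.619 RPKM (n = 5 each, log2 1.47 ± 0.16, adjusted p = 4.82e-05). Clock repressors and output genes fell: Ciart by 2.39 ± 0.42, Dbp by 2.01 ± 0.35, Usp2 by 1.88 ± 0.35, Per3 by 1.58 ± 0.23 and Per1 by 1.29 ± 0.30. The cell cycle kinase gene Wee1 fell by 1.46 ± 0.26. Of 18 tested clock genes, 2 rose, 7 fell and 9 did not pass (4 and 11 adjusted over the list alone). By camera, the adjusted p was 1.86e-05, and adjusted p = 0.322 with an estimated correlation. Camera tests for a shift in a single direction, and clock genes moved in both. Its p therefore says little about the clock list, here and in later comparisons.

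ER chaperone genes were higher with the young WT partner. Hspa5, the main chaperone of the ER lumen, rose from 70.3 ± 16.6 to 127 ± 9.73 RPKM (log2 0.87 ± 0.19), Creld2 by 1.12 ± 0.27 and Hyou1 by 1.08 ± 0.25. With Manf, 4 of 21 tested members rose and none fell (13 rose adjusted over the list alone). At the preset correlation camera gave an adjusted p = 7.03e-11, and adjusted p = 0.322 with an estimated correlation. Of the heat shock list, 0 of 14 passed and 4 rose adjusted over the list alone (median 0.30). This list had a camera adjusted p = 1.81e-04, and adjusted p = 0.638 with an estimated correlation. Of the genes of major urinary proteins, which carry pheromones, Mup11 rose by 3.36 ± 0.76, Mup19 by 1.68 ± 0.39 and Mup2 by 1.23 ± 0.30, while others such as Mup3 (0.59 ± 0.26, adjusted p = 0.261) did not pass. Reads of these near-identical copies cannot be assigned with certainty. Male-biased liver genes had a median of 0.76, with 1 of 23 passing (Nudt7, 1.03 ± 0.25) and 8 adjusted over the list alone. For this list camera's adjusted p was 5.00e-08, and adjusted p = 0.322 with an estimated correlation. Female-biased genes had a median of -0.84, with 0 of 11 passing and 2 lower adjusted over the list alone. The list's adjusted p in camera was 0.00218, and adjusted p = 0.883 with an estimated correlation. Cholesterol synthesis genes had a median of 0.49, with 0 of 24 passing and 10 higher adjusted over the list alone. By camera, the adjusted p was 6.14e-08, and adjusted p = 0.798 with an estimated correlation. Among the 7 lists that camera set lower were MHC class II genes (0 of 6, also adjusted over the list alone; median -0.70), inflammatory cytokines (1 of 14, also adjusted over the list alone; Il1rn fell by 0.74 ± 0.17) and ribosomal proteins (0 of 30, also adjusted over the list alone; median -0.15). Each of these 3 had an adjusted p = 0.905 with an estimated correlation. The call of the MHC class II list was also lost without old-old replicate 4 or replicates 1, 4 or 5 of the WT partner group (adjusted p up to 0.285), and that of the cytokines without old-old replicate 4 or replicates 1 or 5 of the WT partner group (up to 0.393). Interferon-stimulated genes (0 of 23, also adjusted over the list alone; median -0.28) and complement and coagulation genes (1 higher and 1 lower of 25, also adjusted over the list alone; median -0.11) were set lower too, each with adjusted p = 0.0489 (adjusted p = 0.905 with an estimated correlation) and a call that held in 3 of 10 single-library omissions and not after scaling. Singly, the tubulin gene Tubb2a (1.59 ± 0.38) and the manganese exporter gene Slc30a10 (1.14 ± 0.24) rose, while Dsg1c fell by 1.33 ± 0.27 and Upp2 by 1.31 ± 0.31.

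In all, 110 of 9372 genes passed limma's test, 70 higher and 40 lower, and 12 of 37 lists were called by camera, 0 of them with an estimated correlation. The gene count was 58, 231, 34 and 29 without old-old replicates 1, 2, 4 and 5, and 34 and 12 without replicates 1 and 3 of the young WT partner group. It was 317 with limma's weights per library, 48 with no filter on low values, 175 after scaling and 192 with voom. Here and below, voom used library sizes set by median-of-ratios factors, so it is not a check separate from scaling. Arntl, Ciart, Dbp, Per3 and Wee1 passed in all 10 single-library omissions, Manf, Hyou1, Mup19 and Tubb2a in 3, and Creld2, Mup2, Nudt7 and Il1rn in 2. With the phase score as a covariate 0 genes passed (420 at an unadjusted p under 0.05), the median SE was 0.18 instead of 0.10 and Manf stood at 0.53 ± 0.42. The clock and female-biased lists turned to 0.23 and 1.00 relative to all genes in that model. The score is itself made of clock list genes and nearly coincides with pair type, so nothing is read from these turns.

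The second comparison sets a heterozygous young partner against an old partner. Cholesterol synthesis genes rose in the old liver: Sqle, a rate-limiting enzyme of the pathway, went from 3.64 ± 1.66 to 13.6 ± 7.32 RPKM (n = 5 each, log2 1.77 ± 0.48, adjusted p = 0.0113). Mvd rose by 1.49 ± 0.35, Idi1 by 1.48 ± 0.37 and Nsdhl by 1.45 ± 0.36. Of 24 tested members 17 rose and none fell (20 adjusted over the list alone). Camera gave an adjusted p = 3.85e-36, and adjusted p = 0.0159 with an estimated correlation. De novo lipogenesis genes followed, with 6 of 20 higher (11 adjusted over the list alone), among them Thrsp (1.56 ± 0.46), Acacb (1.24 ± 0.43) and Acss2 (1.07 ± 0.33); camera's adjusted p was 8.07e-17, and 0.0307 with an estimated correlation.

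Genes of immune and other non-hepatocyte cells were lower. The MHC class II genes H2-Aa, Cd74, H2-Ab1 and H2-Eb1, which serve antigen presentation, fell by 1.90 ± 0.45, 1.81 ± 0.43, 1.77 ± 0.43 and 1.77 ± 0.47. All 6 tested MHC class II genes fell, also adjusted over the list alone. The B cell markers Cd79a (-1.51 ± 0.27) and Cd79b (-1.27 ± 0.30), the monocyte and macrophage markers Lyz2 (-1.56 ± 0.37) and Lgals3 (-1.33 ± 0.26) and the neutrophil marker S100a9 (-1.04 ± 0.33) fell beside them. For the MHC class II list camera gave an adjusted p = 7.84e-04 at the preset correlation, and adjusted p = 0.324 with an estimated correlation. The lists of B and plasma cells, of monocytes and macrophages and of neutrophils were not called. Old-old replicate 4 held Cd74 at 329.9 RPKM, against 58.8 to 112 RPKM in the rest of its group. Of 23 interferon-stimulated genes 20 fell (22 adjusted over the list alone; 13 after median-of-ratios scaling), among them Gbp2 (-1.60 ± 0.44) and Ifit3 (-1.36 ± 0.28); camera gave an adjusted p = 5.32e-08, and adjusted p = 0.318 with an estimated correlation. Kupffer cell markers fell in 10 of 15 cases (13 adjusted over the list alone), including Adgre1 by 1.48 ± 0.37, Cd68 by 1.32 ± 0.28 and C1qb by 1.28 ± 0.28. This list had a camera adjusted p = 4.79e-04, and adjusted p = 0.447 with an estimated correlation. Its mean log2 level was 2.357 in replicate 4 of the heterozygous partner group, against 3.495 to 3.737 in the rest of that group. Markers of stellate cells and fibroblasts fell in 12 of 14 cases, also adjusted over the list alone, with the collagen genes Col3a1 at -1.27 ± 0.22 and Col1a1 at -1.21 ± 0.24. Camera gave an adjusted p = 1.82e-06, and adjusted p = 0.174 with an estimated correlation. Sinusoidal endothelial markers fell in 11 of 16 cases (14 adjusted over the list alone; 3 after scaling). For this list camera's adjusted p was 8.93e-04, and adjusted p = 0.483 with an estimated correlation. Inflammatory cytokines fell in 8 of 14 (10 adjusted over the list alone), with Ccl5 at -1.97 ± 0.63 and Ccl2 at -1.52 ± 0.39. For this list camera's adjusted p was 0.00388, and adjusted p = 0.447 with an estimated correlation. Singly, Col5a2 fell by 1.98 ± 0.42, Clec7a, a receptor for fungal glucans, by 1.69 ± 0.32 and Cib3 by 1.62 ± 0.59.

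Some hepatocyte lists lay higher than other genes. Periportal hepatocyte markers were lower in 5 of 15 cases, also adjusted over the list alone (2 after scaling, camera adjusted p = 0.7003), where 2126 of all 9372 tested genes were lower. Xenobiotic genes rose in 6 of 26 cases (7 adjusted over the list alone), with Cyp1a2 at 0.82 ± 0.21 and Cyp2c37 at 0.88 ± 0.30, and camera's adjusted p was 1.07e-11, or 0.0307 with an estimated correlation. Bile acid genes rose in 2 of 17 cases, also adjusted over the list alone: the transporter genes Slco1a1 (1.31 ± 0.35) and Slc10a1 (0.53 ± 0.14). The list's adjusted p in camera was 1.13e-06, and adjusted p = 0.0159 with an estimated correlation. Hepatocyte markers passed in 0 of 15 cases, also adjusted over the list alone, with a median of 0.21 relative to all genes. The list's adjusted p in camera was 2.12e-07, and adjusted p = 0.0136 with an estimated correlation. Mup1 (2.82 ± 0.75), Mup12 (2.24 ± 0.66), Mup11 (2.10 ± 0.76), the female-biased Cyp2c69 (1.62 ± 0.55) and Ugt1a5 (1.59 ± 0.43) rose, all from families whose reads are hard to assign. Manf, the clock genes (0 of 18, also adjusted over the list alone) and the ER chaperone list (2 of 21 lower, 0 adjusted over the list alone; camera adjusted p = 0.886) gave no such pattern. Camera set the clock list above other genes all the same, at a median of 0.07 (adjusted p = 2.75e-04, adjusted p = 0.139 with an estimated correlation).

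In all, 2211 genes passed, 85 higher and 2126 lower, and 19 of 37 lists were called, 7 with an estimated correlation. The median of all genes was -0.14, and after median-of-ratios scaling, which moved it to 0.01, 331 genes were higher and 604 lower. Ccl5, S100a9, Mup11 and Cib3 no longer passed then, and ribosomal proteins, 10 of 30 lower as deposited (22 adjusted over the list alone, adjusted p = 0.7004 with an estimated correlation), had 0 lower. Without old-old replicate 4 the gene count was 1318, and 1215 without replicate 4 of the heterozygous partner group. It was 3402 with no filter on low values, 816 at 5 RPKM or more, 1415 with only the groups compared, 898 with voom and 1343 with Alb left out of the read total. Sqle, Mvd, Cd74, H2-Aa, Clec7a and Col5a2 passed in all 10 single-library omissions, S100a9 in 8, Cyp2c37 in 4, Acacb and Mup11 in 3 and Cib3 in 2. The ribosomal list lost its call without old-old replicate 4 or replicate 5 of the heterozygous partner group (adjusted p up to 0.11).

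**Figure D3:**
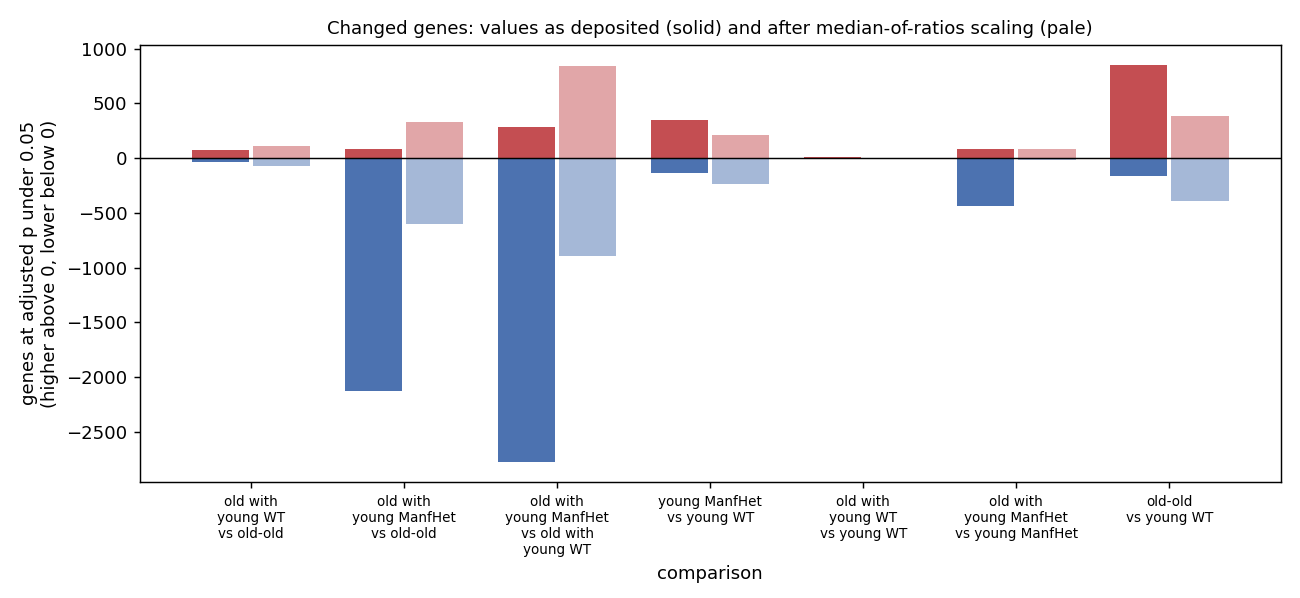
Genes higher (above 0) and lower (below 0) at an adjusted p under 0.05 in 7 comparisons of 5 against 5 livers, for values as deposited (solid bars) and after median-of-ratios scaling (pale bars). In old livers with heterozygous partners against those with WT partners, 288 genes are higher and 2777 lower as deposited, and 837 and 893 after scaling.

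The third comparison sets both kinds of young partner against each other in the old liver. It reuses the livers with young partners of the first and second comparisons, so its results are not independent of theirs. The clock genes that had fallen with the WT partner were higher with the heterozygous partner. Ciart rose by 3.04 ± 0.42, Usp2 by 2.74 ± 0.35, Dbp by 2.11 ± 0.35 and Per1 by 1.79 ± 0.30, with Dbp at 42.0 ± 5.52 against 11.5 ± 7.66 RPKM (n = 5 each). Of 18 clock genes 12 rose and 3 fell, also adjusted over the list alone. By camera, the adjusted p was 1.28e-10, and adjusted p = 0.0157 with an estimated correlation. ER chaperone genes fell in 18 of 21 cases with 1 higher (19 and 1 adjusted over the list alone; 13 and 1 after scaling). Sdf2l1 fell by 1.78 ± 0.34, Creld2 by 1.47 ± 0.27 and Derl3 by 1.47 ± 0.48. At the preset correlation camera gave an adjusted p = 1.05e-05, and adjusted p = 0.358 with an estimated correlation. Heat shock genes fell in 10 of 14 cases, also adjusted over the list alone, with Hsp90aa1 at -1.21 ± 0.23 and Hspb1 at -0.97 ± 0.20. This list had a camera adjusted p = 0.00307, and adjusted p = 0.436 with an estimated correlation.

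Female-biased liver genes rose in 7 of 11 cases (10 adjusted over the list alone), including Cyp2a4 by 2.94 ± 0.77, Acot3 by 2.74 ± 0.63, Cyp2c69 by 2.52 ± 0.55 and Cyp2c40 by 2.04 ± 0.56. Camera gave an adjusted p = 3.62e-12, and adjusted p = 0.0535 with an estimated correlation. Cyp2c69 averaged 14.9 ± 12.2 RPKM with replicate 3 at 36.0, and 2.99 ± 4.56 RPKM in the WT partner group with replicate 5 at 11.1. Hepatocyte markers rose in 5 of 15 cases, also adjusted over the list alone, with Alb, the gene of serum albumin, at 1.10 ± 0.27 and the plasma protein genes Ahsg at 0.34 ± 0.13 and Ttr at 0.31 ± 0.12. For this list camera's adjusted p was 2.96e-07, and adjusted p = 0.0157 with an estimated correlation. Periportal hepatocyte markers fell in 4 of 15 cases, also adjusted over the list alone: Gldc by 0.92 ± 0.18, Cdh1 by 0.81 ± 0.25, Hal by 0.66 ± 0.17 and Ctsc by 0.52 ± 0.18 (2 after scaling, camera adjusted p = 0.307). Of all 9372 tested genes 2777 fell in this comparison, so the periportal share is no larger than that of all genes. Xenobiotic genes rose in 7 of 26 cases (6 adjusted over the list alone), led by the nuclear receptor gene Nr1i3 (1.36 ± 0.33) and Por (1.15 ± 0.22). By camera, the adjusted p was 5.07e-10, and adjusted p = 0.0645 with an estimated correlation. Cholesterol synthesis genes rose in 4 of 24 cases (2 adjusted over the list alone). The list's adjusted p in camera was 5.07e-10, and adjusted p = 0.295 with an estimated correlation.

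Non-hepatocyte markers were lower: 11 of 15 Kupffer genes (12 adjusted over the list alone), 13 of 14 stellate and fibroblast genes (13 adjusted over the list alone) and 12 of 16 sinusoidal endothelial genes (13 adjusted over the list alone) fell, or 10, 7 and 8 after scaling. Adgre1 fell by 1.49 ± 0.37, Cd5l by 1.19 ± 0.28, Col3a1 by 1.01 ± 0.22 and Ehd3 by 0.85 ± 0.19. Camera's adjusted p was 0.00998, 9.48e-04 and 0.00417, and for these lists in that order adjusted p = 0.686, 0.441 and 0.686 with an estimated correlation. Replicate 4 of the heterozygous partner group had a mean log2 Kupffer level of 2.357, against 3.495 to 3.737 in the rest of that group. Interferon-stimulated genes fell in 18 of 23 cases (20 adjusted over the list alone; 9 after scaling). At the preset correlation camera gave an adjusted p = 0.00128, and adjusted p = 0.686 with an estimated correlation. Among single genes, Rgs16 (3.43 ± 0.89), the metallothionein gene Mt1 (2.34 ± 0.72) and Cyp2a5 (2.29 ± 0.39) rose. Elovl3, a fatty acid elongase gene, fell by 2.67 ± 0.56, Tubb2a by 2.32 ± 0.38, Lcn2 by 2.15 ± 0.80 and Selenbp2 by 1.71 ± 0.62. Ddc fell by 1.69 ± 0.28, St5 by 1.58 ± 0.26 and the neutrophil gene S100a9 by 1.57 ± 0.33.

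In all, 3065 genes passed, 288 higher and 2777 lower, and 17 of 37 lists were called, 2 with an estimated correlation. After scaling, which moved the median of all genes from -0.15 to 0.00, 837 genes were higher and 893 lower. Lcn2, Selenbp2, Ctsc and Cdh1 no longer passed after scaling, and they passed in 3, 4, 4 and 8 of 10 single-library omissions, Ahsg and Ttr in 2. Without replicate 4 of the heterozygous partner group the gene count was 1957. At 5 RPKM or more it was 1444, with voom 1704 and with Alb left out of the read total 1993. With the phase score as a covariate 0 genes passed (512 at an unadjusted p under 0.05), with a median SE of 0.20 instead of 0.10 and Manf at -0.74 ± 0.47.

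**Figure D4:**
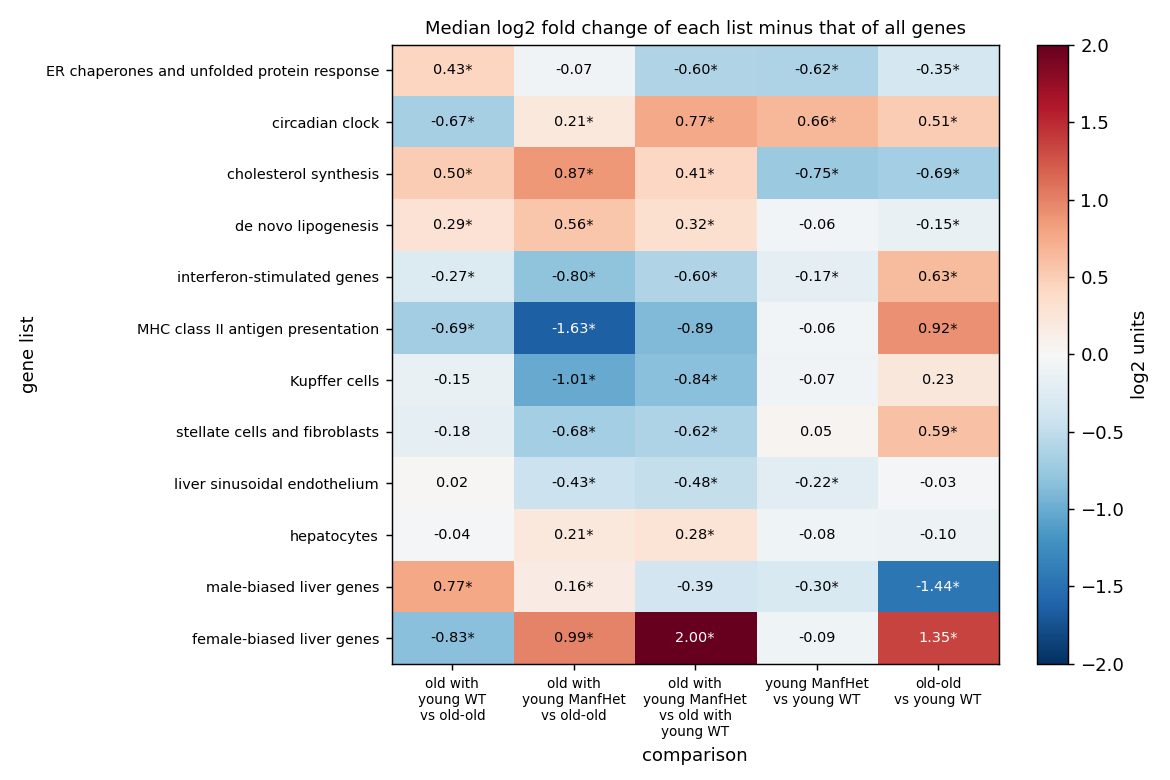
Median log2 fold change of 12 fixed gene lists minus that of all tested genes (colour and number) in 5 comparisons of 5 against 5 livers, with an asterisk where camera's adjusted p with the preset correlation was under 0.05. Relative to all genes, the ER chaperone list lies at 0.43 in old livers with WT partners against old-old livers, and at -0.60 and -0.62 in the old and the young livers of heterozygous against WT pairs.

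The fourth comparison is between the young partners, heterozygous against WT. Clock genes rose in 10 of 18 cases and fell in 3 (11 and 3 adjusted over the list alone), with Usp2 at 2.28 ± 0.35, Ciart at 2.22 ± 0.42, Dbp at 1.59 ± 0.35 and Per3 at 1.35 ± 0.23. By camera, the adjusted p was 0.00288, and adjusted p = 0.519 with an estimated correlation. ER chaperone genes fell in 10 of 21 cases (16 adjusted over the list alone). Beside Manf, Sdf2l1 fell by 1.56 ± 0.34, Creld2 by 1.05 ± 0.27 and Calr by 0.85 ± 0.20. At the preset correlation camera gave an adjusted p = 8.74e-17, and adjusted p = 0.255 with an estimated correlation. Cholesterol synthesis genes fell in 9 of 24 cases (19 adjusted over the list alone). Sqle went from 10.7 ± 4.40 to 3.05 ± 2.75 RPKM (n = 5 each, log2 -1.91 ± 0.48). Hmgcs1 fell by 1.66 ± 0.34, Mvd by 1.43 ± 0.35 and Idi1 by 1.40 ± 0.37. This list had a camera adjusted p = 2.33e-18, and adjusted p = 0.294 with an estimated correlation. Acute phase genes had a median of -0.47, with 1 of 20 lower, also adjusted over the list alone (Crp, -0.39 ± 0.11). This list had a camera adjusted p = 1.38e-08, and adjusted p = 0.519 with an estimated correlation.

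Hamp, which encodes the iron hormone hepcidin, rose by 2.04 ± 0.47, the haem synthesis gene Alas1 by 1.72 ± 0.41, the lipid transporter gene Mfsd2a by 1.67 ± 0.36, Tsku by 1.54 ± 0.44 and Wee1 by 1.51 ± 0.26. The immediate-early gene Egr1 fell by 2.08 ± 0.36, Tubb2a by 1.84 ± 0.38 and Acnat2 by 1.72 ± 0.40. Egr1 stood at 11.4 RPKM in young WT replicate 2 against 2.17 to 4.76 in the rest of that group, and the same library alone held the pancreatic gene Prss2 at 48.0 RPKM. In all, 481 genes passed, 349 higher and 132 lower, or 215 higher and 234 lower after scaling (Tsku not among them), and 9 of 37 lists were called, 0 with an estimated correlation. Without young WT replicates 2, 3 and 5 the gene count was 140, 238 and 731, and without young heterozygous replicates 2, 3, 4 and 5 it was 167, 150, 164 and 829. Tsku passed in 3 and Crp in 2 of 10 single-library omissions, Manf in all. The count was 165 without both libraries that held muscle or pancreas transcripts, 1122 with weights per library, 279 with no filter and 173 with only the groups compared. With the phase score as a covariate 0 genes passed (573 at an unadjusted p under 0.05), with a median SE of 0.16 instead of 0.10 and Manf at -1.22 ± 0.37.

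Age was compared in 3 ways, with each young group made up of mice joined to old ones. Age was not the only difference. Old-old and young WT livers came from different kinds of pair, with mean phase scores of -3.26 and -1.75. In the other comparisons the old livers had a young partner and the young livers an old one. In the heterozygous pairs Manf genotype differed too. Effects of age cannot be told apart from these. Partners were not matched in the main fits, since the labels do not give the pairs. Against young WT livers, old-old livers had higher Noct, a rhythmic gene whose product acts on NADPH, at 17.2 ± 10 against 0.805 ± 0.271 RPKM (n = 5 each, log2 3.55 ± 0.41, adjusted p = 8.39e-05). Male-biased liver genes fell in 14 of 23 cases (19 adjusted over the list alone), with Mup7 at -4.06 ± 0.82, Mup1 at -3.50 ± 0.75, Selenbp2 at -2.97 ± 0.62 and Hsd3b5 at -2.89 ± 0.45. Camera gave an adjusted p = 2.07e-25, and adjusted p = 0.0114 with an estimated correlation. Female-biased genes rose in 3 of 11 cases (7 adjusted over the list alone), including Cyp2a4 by 2.64 ± 0.77 and Slc22a26 by 2.37 ± 0.55. For this list camera's adjusted p was 0.00330, and adjusted p = 0.591 with an estimated correlation. The sex-chromosome genes Ddx3y (0.002 ± 0.098), Uty (0.013 ± 0.068), Eif2s3y (0.047 ± 0.106) and Kdm5d (0.114 ± 0.069) did not pass in this comparison, and their list was not called. Markers of stellate cells and fibroblasts rose in 8 of 14 cases (9 adjusted over the list alone), including Col1a1 by 0.97 ± 0.24 and Bgn by 0.92 ± 0.20. The list's adjusted p in camera was 7.72e-04, and adjusted p = 0.591 with an estimated correlation. Clock genes rose in 10 of 18 cases and fell in 3 (13 and 4 adjusted over the list alone), with a camera adjusted p = 0.0188, and adjusted p = 0.591 with an estimated correlation. Interferon-stimulated genes rose in 8 of 23 cases (14 adjusted over the list alone; 3 after scaling), with Irf7 at 1.07 ± 0.25. Inflammatory cytokines rose in 5 of 14 (7 adjusted over the list alone), with Ccl2 at 1.53 ± 0.39. Camera gave adjusted p = 2.20e-04 and 0.0219 for these lists, and each had an adjusted p = 0.607 with an estimated correlation. Cholesterol synthesis genes fell in 12 of 24 cases (14 adjusted over the list alone), with Nsdhl at -1.34 ± 0.36 and Mvd at -1.34 ± 0.35. ER chaperone genes fell in 3 of 21 (6 adjusted over the list alone), with Creld2 at -0.94 ± 0.27 and Hyou1 at -0.86 ± 0.25. For these lists camera gave adjusted p = 4.07e-15 and 8.56e-11, and for each adjusted p = 0.261 with an estimated correlation.

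In that comparison 1017 genes passed, 854 higher and 163 lower, or 383 and 388 after scaling, and 17 of 37 lists were called, 1 with an estimated correlation. The gene count was 613 and 467 without young WT replicates 2 and 3, 411 (with 11 lists) and 642 without old-old replicates 4 and 5, and 1 with the phase score as a covariate (1374 at an unadjusted p under 0.05). At 5 RPKM or more it was 527, and 473 with only the groups compared. Creld2 and Hyou1 passed in 5 of 10 single-library omissions, and the cytokine list lost its call without young WT replicates 1 or 5 or old-old replicate 4 (adjusted p up to 0.106).

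Old livers with young WT partners, against those partners, had 11 genes higher and 0 lower, with 1187 at an unadjusted p under 0.05. That count moved with the settings: 58 genes passed with weights per library, 41 with no filter, 17 with Alb left out of the read total, 7 at 5 RPKM or more, 7 with a block for replicate number, 5 with voom and 4 with only the groups compared. Noct rose by 2.72 ± 0.41, the protease inhibitor gene Serpinb1a by 2.23 ± 0.42 and Gpx3, a secreted glutathione peroxidase gene, by 1.31 ± 0.17 (2.00 ± 0.42 to 5.78 ± 1.47 RPKM, n = 5 each). Raet1e (1.23 ± 0.23), Ehbp1l1 (0.75 ± 0.11), Trim30d (0.75 ± 0.15), Pdgfrb (0.75 ± 0.15) and Htatip2 (0.73 ± 0.14) rose as well. Acsm3 (-0.45 ± 0.10), Slc39a4 (-0.83 ± 0.18) and Mup21 (-1.16 ± 0.25) had an adjusted p = 0.0561 and Mir6236 (-1.43 ± 0.34) 0.0853, the lowest p among lower genes that did not pass. Male-biased genes had a median of -0.60, with 0 of 23 passing and 2 lower adjusted over the list alone. By camera, the adjusted p was 5.47e-19, and adjusted p = 0.0389 with an estimated correlation. After scaling 4 genes were higher and 1 lower, and Serpinb1a, Raet1e, Trim30d, Pdgfrb and Htatip2 no longer passed. The gene count was 6, 6 and 7 without young WT replicates 1, 3 and 5, 7, 4, 28 and 7 without replicates 2, 3, 4 and 5 of the old group, and 6 with the phase score as a covariate. Noct, Gpx3 and Ehbp1l1 passed in all 10 single-library omissions, Serpinb1a in 4, Htatip2 in 2 and Pdgfrb and Trim30d in 1.

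Old livers with heterozygous partners, against those partners, had female-biased genes higher in 8 of 11 cases (9 adjusted over the list alone). Cyp2c69 rose by 3.87 ± 0.55, Cyp2b9 by 3.51 ± 0.94, Cyp2a4 by 3.49 ± 0.77 and Cyp2c40 by 3.30 ± 0.56. At the preset correlation camera gave an adjusted p = 1.63e-25, and adjusted p = 0.00296 with an estimated correlation. Cholesterol synthesis genes rose in 16 of 24 cases (23 adjusted over the list alone), with Sqle at 2.21 ± 0.48 and Hmgcs1 at 1.68 ± 0.34. This list had a camera adjusted p = 4.08e-50, and adjusted p = 0.00359 with an estimated correlation. Hepatocyte markers rose in 3 of 15 cases (5 adjusted over the list alone), namely Alb by 1.24 ± 0.27, Trf by 0.58 ± 0.11 and F2 by 0.24 ± 0.07. Camera gave an adjusted p = 1.11e-11, and adjusted p = 0.00169 with an estimated correlation. Male-biased genes fell in 9 of 23 cases (11 adjusted over the list alone), with Mup21 at -1.75 ± 0.25 and Gstp1 at -1.62 ± 0.25. For this list camera's adjusted p was 8.28e-04, and adjusted p = 0.440 with an estimated correlation. Kupffer markers fell in 3 of 15 cases (12 adjusted over the list alone), with Cd163 at -0.96 ± 0.28 (0 after scaling). Camera gave an adjusted p = 0.00516, and adjusted p = 0.563 with an estimated correlation. In all, 520 genes passed, 85 higher and 435 lower, or 84 and 17 after scaling, which moved the median of all genes from -0.13 to -0.01 and ended the calls of Cyp2b9 and Cd163. By camera 17 of 37 lists were called, 3 with an estimated correlation. Weights per library gave 1976 genes, no filter 232, a block for replicate number 188, only the groups compared 99, Alb left out of the read total 92 and voom 83. The gene count was 40, 18, 33 and 1508 without young heterozygous replicates 1, 2, 4 and 5, and 207, 112, 192, 75 and 1086 without replicates 1 to 5 of the old group. Cyp2b9 and F2 passed in 3 of 10 single-library omissions and Cd163 in 1, and the Kupffer list lost its call without young heterozygous replicate 5 or old replicate 4 (adjusted p up to 0.0802).

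Whether the difference between old and young partners itself depended on the young partner's genotype was tested as an interaction. Cholesterol synthesis genes differed as a group, by a median of 1.13 relative to all genes, with 22 of 24 higher adjusted over the list alone but 0 over all genes. The list's adjusted p in camera was 1.80e-57, and adjusted p = 0.00258 with an estimated correlation. Female-biased genes differed by 1.57 (0 of 11, 2 adjusted over the list alone; 0.00856 with an estimated correlation). Hepatocyte markers differed by 0.35 (0 of 15, 3 adjusted over the list alone; 3.21e-04 with an estimated correlation) and stellate and fibroblast markers by -0.48 (0 of 14, 9 lower adjusted over the list alone; adjusted p = 0.404 with an estimated correlation). Over all genes limma called 1, Ngrn, at -0.47 (adjusted p = 0.0377), with 2937 genes at an unadjusted p under 0.05. With weights per library 2036 genes were called, with no filter 6 and with a block for replicate number 3, but 0 after scaling, with voom, with only the groups compared, with Alb left out or with the phase score as a covariate (at least 790 at an unadjusted p under 0.05 each time). The count was 12 and 914 without young WT replicate 4 and young heterozygous replicate 5. It was 1234 without replicate 4 of the old group with WT partners, 17 and 679 without replicates 1 and 5 of the old group with heterozygous partners, and 718 without both libraries that held muscle or pancreas transcripts. It was 0 without young WT replicates 1, 2, 3 or 5, young heterozygous replicates 1, 2 or 4, replicates 1, 2 or 3 of the old group with WT partners, or replicates 2 or 4 of the old group with heterozygous partners, with at least 2210 genes at an unadjusted p under 0.05 each time. Ngrn itself was lost in these omissions and without replicate 5 of the old group with WT partners, 13 of 20 in all.

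Genes linked to age were followed in the old liver, each set taken from an age comparison that shared no library with the comparison tested. Such a set carries whatever else differed in its age comparison. The sets for heterozygous against WT partners came from old-old against young WT livers, whose mean phase scores were -3.26 and -1.75. Old livers with heterozygous and with WT partners differed the same way, at -3.57 and -1.19. Movement of those sets cannot be told apart from this shared phase difference. With a young WT instead of an old partner, 85 genes higher and 200 genes lower in old livers had medians of 0.01 and 0.03 relative to all genes (camera adjusted p = 0.628 and 0.408). With sets and test remade after scaling, the lower set shrank to 17 genes with a median of 0.17 (adjusted p = 0.0281). With a heterozygous instead of an old partner, the 11 genes higher in old livers had a median of -0.16 relative to all genes, and 5 of them fell (camera adjusted p = 0.387). Remade after scaling, that set held 4 genes with a median of -0.31 (adjusted p = 0.0272). With a heterozygous instead of a WT partner, 200 genes higher in old livers had a median of -0.06, which lay 0.08 above that of all genes, so that camera's direction was up while 21 rose and 39 fell (adjusted p = 2.62e-05, adjusted p = 0.508 with an estimated correlation). Remade after scaling, the median was 0.06 (adjusted p = 0.0152). The 163 genes lower in old livers lay at -0.13 relative to all genes in that comparison, with 3 higher and 57 lower. Their camera adjusted p was 0.0895, and 0.631 with an estimated correlation. With the set and the test remade after scaling, it was 1.18e-05 at the preset correlation.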

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

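Several levels and list differences stood apart, and of the tests below those of the clock genes in old against young livers, of the 10 most abundant genes and of the non-hepatocyte lists were chosen only after the result was seen. The phase score itself was also defined after the clock genes had been seen. A single library far from the other 4 of its group was sought for 23 quantities in 5 groups each (115 tests), and 11 were found. About 5% of tests would find one by chance, but since genes were chosen for this after their values had been seen, the 11 cannot be set against that rate.

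In old-old livers, replicate 3 held Creld2 at 15.9 RPKM (others 5.91 to 8.57), replicate 4 held Cd74 at 329.9 (58.8 to 112) and Adgre1 at 21.92 (5.957 to 9.999), and replicate 2 held Mup7 at 363.4 (7.24 to 77.8). Arntl stood at 0.4696 RPKM in replicate 5 of old livers with heterozygous partners (others 0.0469 to 0.1397), and Cyp2c69 at 36 in replicate 3 (5.11 to 13.5). In old livers with WT partners, Cyp2c69 stood at 11.14 RPKM in replicate 5 (others 0.617 to 1.17), and the muscle gene Acta1 at 58.08 in replicate 4 (0.0490 to 0.188). Young heterozygous replicate 1 held Tubb2a at 16.91 RPKM (others 3.15 to 6.84). Young WT replicate 2 held Egr1 at 11.37 RPKM (2.17 to 4.76) and the pancreatic gene Prss2 at 47.96 (0 to 0.1002).

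The difference between old and young livers of the same pair type, fitted without matching partners, differed by partner genotype for Ngrn (-0.474, limma adjusted p = 0.0377) and for 18 lists. Ngrn was at 0.18 in WT pairs and -0.30 in heterozygous pairs. Relative to all genes the list medians differed by 1.133 for cholesterol synthesis, 1.571 for female-biased genes, 0.346 for hepatocyte markers and 0.291 for gluconeogenesis, and these 4 held with an estimated correlation (p = 0.00258, 0.00856, 3.21e-04 and 0.0213). The other 14 did not hold with an estimated correlation. They were ER chaperones (0.047), ATF4 targets (0.055), acute phase (0.145), stellate cells and fibroblasts (-0.478), pericentral hepatocytes (0.222), de novo lipogenesis (0.371), fatty acid oxidation (0.166), bile acids (0.114), xenobiotic metabolism (0.268), male-biased genes (-0.181), clock genes (0.275), immediate-early genes (0.018; -0.01 after scaling), the growth hormone and IGF axis (0.002) and complement and coagulation (0.223). For male-biased genes camera's direction was up although the median was lower than that of all genes. For them and for ER chaperones, ATF4 targets, acute phase, bile acid, fatty acid oxidation, immediate-early and growth hormone genes, the median as deposited was negative while the test pointed up.

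The first pattern is that clock and ER chaperone genes differed by pair type in old and young livers alike: over 18 clock genes the heterozygous against WT difference in old livers followed that in young livers with r = 0.97, although these comparisons share no library. Livers of WT pairs could have been collected at another time of day, which the sources used here do not give, and a clock set by the shared circulation predicts the same value. ER chaperone levels followed the phase score within groups (Pearson r = 0.46, permutation p = 0.0129; Spearman rho 0.44, p = 0.0298; r = 0.48 without the 2 farthest livers), so part of the ER difference may go with phase. With phase as a covariate the ER list lay at -0.03 relative to all genes in old livers with WT against old partners, at 0.01 with heterozygous against WT partners and at -0.20 between the young groups (camera adjusted p = 0.771, 0.967 and 2.04e-04), but phase nearly coincides with pair type, so that model can hardly separate them. Outside the clock list, 194 genes were called in the same direction in both ages against 48.3 for independent calls, a ratio of 4.02 (6.75 after scaling, 271 against 40.2). In opposite directions 3 were called (0 after scaling). Both comparisons share each gene's SE from the single model, so genes of small spread are more easily called in both. The ratio may be inflated by this. The differences of all these genes had r = 0.57, so collection time, handling of the pair types and the shared circulation all stay open.

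The second pattern is the excess of lower genes in old livers with heterozygous against WT partners (90.6% of calls, 88.8 to 92.5% with single libraries left out). Alb took up 14.9 ± 3.77% of gene reads in the former and 7.42 ± 2.96% in the latter (exact p = 0.0238, 0.0556 adjusted over 7 comparisons), which could lower all other values. With Alb left out of the read total, 80.3% of 1993 calls were lower (75.7 to 82.7% with single libraries left out), just past the limit of 80% set beforehand, above which Alb would not be the cause, but that limit fell inside the spread, so the test is read as undecided, a reading adopted after the value was seen. With the 10 most abundant genes left out, 76.5% of 1832 calls were lower (71.9 to 80.2%), also undecided, and that test took the place of an earlier choice, median-of-ratios scaling, which centres the differences by construction and so could not answer the question. The median of all genes moved from -0.15 to -0.08 and -0.06, so abundant genes may account for a part of the excess, and a lower level of many transcripts remains open.

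The third pattern is the lower level of non-hepatocyte markers in the same comparison: the mean log2 level of Kupffer, sinusoidal endothelial and stellate markers differed by -0.90, -0.55 and -0.73 (exact p = 0.00794 each), that of B and plasma cell markers by -0.58 (exact p = 0.0556; Derl3, at -1.47 its only gene past the test, and Xbp1 are in the ER chaperone list too, so this shift is not separate from that of the ER genes), and those of monocyte, neutrophil and erythroid markers by -0.64, -0.84 and -1.04 (exact p = 0.00794, 0.00794 and 0.0159). The Kupffer shift includes replicate 4 of the heterozygous partner group at 2.357, against 3.495 to 3.737 in the rest of that group. A smaller share of non-hepatocyte cells could lower all these markers alike. The lowest adjusted p over the 6 pairs of the first 4 lists was 0.5952, and 0.5185 over the 21 pairs of all 7, so their shifts could not be told apart, which with 5 livers per group does not show that they are equal. Scale is not the whole of it, since after median-of-ratios scaling 10 of 15 Kupffer, 7 of 14 stellate and 8 of 16 endothelial genes were still lower (11, 13 and 12 as deposited), but it may be a part, and 0 of 5 erythroid genes were lower then (3 as deposited). A change of expression within those cells stays open and was not tested.

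The same libraries were split in 100 ways, the real split among them, out of 126 possible ones. For the interaction, labels were instead shuffled at random within the old livers with young partners and within the young livers, where repeats were possible. The number of splits with a result as large, the real split included, is given here with the real value and the highest other value. For genes called it was 2 (110 and 204) for old livers with WT against old partners, 1 (2211 and 1476) for heterozygous against old, 1 (3065 and 2759) for heterozygous against WT, and 2 (481 and 631) between the young groups. It was 2 (11 and 11) for old livers with WT partners against those partners, 2 (520 and 1317) for the heterozygous pairs and 1 (1017 and 617) for old-old against young WT. Each of these 7 lies under 5% when read singly, without adjustment over the comparisons. The splits also treat livers as independent, which joined partners need not be, so chance is not called excluded. For the interaction it was 3 (1 and 1), which says little for a single gene that was lost in 13 of 20 single-library omissions and after scaling. Another split called more genes than the real split for WT against old partners, for the young groups and, at 1317 against 520, for the heterozygous pairs, so a grouping other than the real one separates some of those livers further, and what sets it was not tested. For lists called, in the same order, it was 55 (12 and 22), 16 (19 and 25), 15 (17 and 19), 64 (9 and 21), 40 (13 and 20), 8 (17 and 18), 10 (17 and 20) and 7 (18 and 20), so chance was not excluded for the number of lists in any of them. For the gap between age-linked sets it was 95 (0.01 and 0.28) and 17 (0.21 and 0.34) for WT against old and heterozygous against WT partners, where chance was not excluded. For heterozygous against old partners only 1 set of 11 genes was available, so no gap could be formed; for the distance of its median from that of all genes it was 2 (0.16 and 0.17), but camera did not call that set, and nothing is claimed for it.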

How the results depend on the processing

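Voom on recovered reads, Alb left out, phase as a covariate and the omission of both libraries with muscle or pancreas transcripts were added after first results were seen (the limit for the test with Alb left out was written before that test was run). Count-based tests were planned only for a table of raw counts and were not run on this RPKM table, although reads could be recovered. The comparisons are written as WT-old, Het-old, Het-WT (old livers by partner), young (heterozygous against WT), WT-pair and Het-pair (old against own young partner), old-young (old-old against young WT) and interaction. Except where fewer genes or libraries were used, the cause was not tested. Genes called, with no filter: WT-old 48, Het-old 3402, young 279, WT-pair 41, Het-pair 232, interaction 6; lists young 14, WT-pair 20. At least 5 RPKM: Het-old 816, Het-WT 1444, WT-pair 7, old-young 527. Median-of-ratios scaling: WT-old 175, Het-old 935, Het-WT 1730, WT-pair 5, Het-pair 101 (11 lists), interaction 0 (791 at an unadjusted p under 0.05); Manf in old-young -0.790 (exact p = 0.0397); age-linked genes lower in old, WT-old 0.168 (p = 0.0281) and Het-WT -0.110 (p = 1.18e-05), higher in old, Het-old -0.308 (p = 0.0272), with sets remade to 17, 200 and 4 genes. Only the groups compared: Het-old 1415, young 173, WT-pair 4, Het-pair 99, old-young 473, interaction 0 (2964 unadjusted). Weights per library: WT-old 317, young 1122, WT-pair 58, Het-pair 1976, interaction 2036. Replicate number as a block: WT-pair 7, Het-pair 188, interaction 3; equal numbers did not pair the livers by the rule that each pair exceed r = 0.1 (r 0.08 to 0.27 in the WT pairs, 4 of 5 above 0.1, mean 0.20 against -0.05 for unequal numbers, where 3 of 5 young and 3 of 5 old livers were closest to their own number, and -0.13 to 0.23 in the heterozygous pairs, 2 of 5 above 0.1, mean 0.05 against -0.01, where 0 of 5 young and 2 of 5 old livers were closest to their own number). Lists called with an estimated correlation: WT-old 0, Het-old 7, Het-WT 2, young 0, WT-pair 2, Het-pair 3, old-young 1, interaction 4; age-linked genes higher in old, Het-WT, -0.063 (p = 0.508). Voom, with library sizes set by median-of-ratios factors and so not separate from scaling: WT-old 192, Het-old 898, Het-WT 1704, WT-pair 5, Het-pair 83, interaction 0 (790 unadjusted). Alb left out: Het-old 1343, Het-WT 1993, WT-pair 17, Het-pair 92, interaction 0 (1457 unadjusted). Phase as a covariate: WT-old 0 (420 unadjusted), Het-WT 0 (512), young 0 (573), WT-pair 6, old-young 1, interaction 0 (2319); in WT-old the female-biased list turned to 1.005 and the clock list to 0.226. Without both libraries with muscle or pancreas transcripts: young 165, interaction 718.

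With each library left out in turn, genes called ranged over WT-old 12 to 231, Het-old 1215 to 2793, Het-WT 1957 to 3486, young 140 to 829, WT-pair 4 to 28, Het-pair 18 to 1508, old-young 411 to 1332 and interaction 0 to 1234, the report naming each library that moved a count by over 1.5 times. Lists ranged over 9 to 14, 18 to 22, 17 to 18, 6 to 13, 11 to 15, 14 to 17, 11 to 19 (11 without old-old replicate 4) and 15 to 20 in that order. Manf ranged over 0.86 to 1.11, -0.41 to -0.17, -1.38 to -1.16, -1.73 to -1.41, 0.15 to 0.47, 0.51 to 0.72 and -0.84 to -0.51. Its exact p in the Het-pair comparison rose above 0.05 without old replicate 5 (0.0635) or young replicates 3, 4 or 5 (0.0556 each), and in old-young it fell under 0.05 without young WT replicate 1 (0.0397) or old-old replicate 3 (0.0476). Pseudocounts of 0.1 and 1 and sets of up to 100 or 500 age-linked genes moved no count by over 1.5 times and ended no call of a Manf or age-linked result. Of the log2 fold changes of genes selected by the rule or named, 5 lost their call with a pseudocount of 0.1, 2 with 1, 17 with scaling, 43 with only the groups compared, 22 with a block and 26 with voom, and none reversed. Depth limits genes near 1 RPKM, where the added 0.5 shrinks the change.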

Other observations

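The list tests below were planned, and which of them to describe here was chosen after the results were seen. Genes of growth hormone signalling, which sets the sex pattern of the liver, had 0 of 13 members past the test in old livers with WT partners against those partners (2 higher and 1 lower adjusted over the list alone; median -0.18, camera adjusted p = 0.00230, and 0.0389 with an estimated correlation). Oxidative phosphorylation genes, which make up the respiratory chain, were lower in 6 of 28 cases in old livers with heterozygous partners against those partners (16 adjusted over the list alone; 0 after scaling; camera adjusted p = 1.53e-04, adjusted p = 0.563 with an estimated correlation). Ribosomal protein genes were higher in 5 of 30 cases in old-old against young WT livers (19 adjusted over the list alone; 0 after scaling; camera adjusted p = 1.73e-05, adjusted p = 0.607 with an estimated correlation). All 6 MHC class II genes were higher there adjusted over the list alone, and 0 over all genes (median 1.00, camera adjusted p = 0.0281, adjusted p = 0.607 with an estimated correlation). The B cell markers Cd79a (1.37 ± 0.27, adjusted p = 0.00411) and Cd79b (1.22 ± 0.30, adjusted p = 0.0151) and the monocyte and macrophage marker Lgals3 (1.07 ± 0.26, adjusted p = 0.0129) rose beside them. The lists of these cells and of Kupffer cells were not called there. Of the Kupffer markers, Cd163 fell (-1.005 ± 0.279, adjusted p = 0.0253) and Slc40a1 rose (0.632 ± 0.144, adjusted p = 0.00957). The call of the MHC class II list was lost without young WT replicates 1, 4 or 5 or old-old replicate 4 (adjusted p up to 0.132).

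Hsd3b5, a male-biased steroid enzyme gene, stood at 131 ± 26.1 and 125 ± 40.5 RPKM in young WT and heterozygous livers, 54.5 ± 27.3 and 40.3 ± 18.4 RPKM in the old livers joined to them and 19.6 ± 11.8 RPKM in old-old livers (n = 5 each). Noct stood at 0.805 ± 0.271 and 1.53 ± 0.553 RPKM in the young groups, 8.72 ± 4.40 and 8.22 ± 5.15 RPKM in the old livers joined to them and 17.2 ± 10 RPKM in old-old livers. Between old groups, Hsd3b5 with WT against old partners (1.422 ± 0.447, limma adjusted p = 0.104) did not pass. Nor did Noct with heterozygous against old partners (-0.996 ± 0.409, limma adjusted p = 0.0769). The first principal component of all tested genes held 25.3% of the variance and the second 18.9%.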
